A study of Mus musculus with 11 samples.

How the data were processed

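Lungs of tumour-bearing mice were digested with collagenase type 2, trypsin and DNase I, live cells were sorted, and RNA was extracted from the sorted fractions with a micro-scale column kit, per the labels' protocols. The sort used the reporters and a viability dye, and no antibody gate for a cell lineage is named there. Complementary DNA was made and amplified with a low-input SMARTer kit, libraries were made with Nextera XT, and paired ends were sequenced on an Illumina instrument, per the labels' protocols. This kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

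The table of 37766 rows and 11 columns holds log2 values that the authors had normalized and transformed before they were deposited. The submitters' processing notes name the mm10 build, FastQC 0.11.8 and DESeq2, without their roles. The aligner, the counting tool and the annotation release are not given in the sources used here. All columns share a floor of 0.482 and reach at most 21.1, the shape of a variance-stabilising transform, which tends to log2 at high values. Undoing that transform gave normalised read counts, and multiplying by the size factor of each library gave whole reads for 100.0% of 145371 values of up to 1000 reads, within a tolerance of 0.1 read. The log2 scale and the read counts were recovered from the values in this way and are not stated by the submitters.

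The table lists 37620 distinct gene identifiers, of which 123 stand on more than 1 row with identical values and were used once. Symbols were found for 32897 identifiers in a mouse reference annotation and for 7 more in the table alone. A further 22531 genes of the reference, with higher identifier numbers than the last one listed, were not analysed here. No reporter transcript was analysed here. Of the listed genes 12936 had no read in any library. Genes with near-identical copies, such as lysozyme, haemoglobin and immunoglobulin genes, are uncertain because the handling of shared reads is not given in the sources used here.

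Libraries held 9741373 to 32354805 reads in listed genes. Counting intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. A gene with no read in a group was given a floor of 3 reads over the group, and its fold is printed as a lower bound. Such a bound does not cover transcripts lost before sequencing. One YFP-positive column could be tied to its group but not to a replicate number. No 2 libraries of a group were alike within sampling noise.

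All 11 libraries were fitted in 1 model with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no replicate block, and each pair of fractions was compared. The plan assumed log2(value + 1) of linear values. As the deposited values were already on a log2 scale, they were tested as they stood, and log2(value + 1) of the back-transformed values became an alternative. Genes needed a normalised count of at least 10 in at least 3 libraries, which left 16362. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A log2 fold change is the difference of group means of the deposited log2 values, printed ± its SE, while fold values are ratios of mean normalised counts and can differ from it. Group levels are mean ± SD.

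Gene lists were tested with camera in limma, which compares a list with all other tested genes, at a preset correlation of 0.01 and adjusted over the lists of a comparison. The 29 lists hold 507 genes, 501 of them with a row, and cover macrophage core, alveolar macrophage, interstitial macrophage, monocyte, neutrophil, dendritic cell, T and NK cell, B and plasma cell, red cell and platelet, mast cell and basophil, endothelial, mesenchymal, mesothelial, alveolar type 2, alveolar type 1, club and ciliated cell, epithelial, cell cycle inhibitor and senescence, secreted senescence factor, cell cycle, immune suppression, MHC class II, lysosome, lipid, interferon, MAPK, BCL2 family, dissociation stress and mitochondrially encoded genes. With the correlation estimated per list, the calls that held were the senescence list between mCherry-positive and negative cells (adjusted p = 0.032) and the mast cell and lipid lists between YFP-positive and negative cells (0.044 and 0.031).

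Groups, tests, lists, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined. By that rule the text may name Cdkn2a, Cdkn2b, Cdkn1a and Kras, per comparison the 5 genes of largest log2 fold change each way among those past the threshold with groups that do not overlap, a mean of at least 100 in the higher group and a symbol that is not of a predicted gene, and per list up to 4 members of smallest adjusted p, up to 2 members that went against the majority or, where none passed, the member of highest mean. Some genes the rule allows were left out of the text.

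The steps were tested on simulated counts for the 16362 genes with 200 changed ones. The changed genes were drawn from those above a minimum mean count, so recovery among genes with few reads is not covered. With 1 spread for all groups, 16.4, 47.8 and 86.4% of genes changed by 2, 4 and 16 times were recovered between mCherry-positive and negative cells, 6.0, 37.3 and 69.7% between mCherry-positive and YFP-positive cells, and 6.0, 34.3 and 75.8% between YFP-positive and negative cells, and 5, 8 and 4 unchanged genes were called. With each group's own spread, 368, 334 and 37 unchanged genes were called, of which 351, 281 and 35 were lower in the first-named group, because genes of equal mean but wider spread have a lower mean on a log2 scale. None of 28 unchanged lists was called in any of these simulations. Those lists were random genes simulated independently of each other, while members of real lists vary together (estimated correlation 0.664 for endothelial genes). The simulations therefore do not show how often the list test at the preset correlation calls unchanged lists of correlated genes.

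Alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, quantile normalization, size factors from tested genes, the replicate number as a block, fits of 2 groups alone, weights per library, a log2 fold change of at least 1, an estimated correlation, and leaving out each library. Added after the data were seen were log2(value + 1), scaling to library totals, thinning to equal depth, limma voom on the recovered reads, weights per group, and only genes with a mean of at least 1000. Coordinates are those of a reference annotation of the mm10 build. Other tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.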

Results

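RNA was sequenced from 11 libraries of cells sorted from tumour-bearing mouse lungs 8 weeks after tumours were started with an adenovirus carrying Cre recombinase. The animals carried a mutant Kras allele, which drives the tumours, a p16 reporter allele that marks cells using the p16 gene with the red protein mCherry, and a yellow fluorescent protein (YFP) switched on by Cre. Per the labels, the sort gave a YFP-positive fraction of tumour cells (n = 3), an mCherry-positive fraction of cells with an active p16 reporter (n = 4), and a fraction negative for both, the rest of the lung (n = 4, called negative here). The labels call the libraries of a group biological replicates but do not say which came from the same animal, so p-values measure the spread between these libraries. The column of one YFP-positive library carries a number that no label of its group has, so it was tied to no single sample and is called unnumbered. Values printed after a gene without a unit are log2 fold changes ± SE.

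Depth and complexity differed between the fractions. Reads in listed genes came to 21282145, 25510032, 24079314 and 24886679 in the negative libraries, 30459894, 32354805 and 20339540.0 in the YFP-positive libraries, and 13124382, 11081584, 16015325 and 9741373 in the mCherry-positive libraries. After thinning each library to 9741373 reads, 12069 to 12881 genes had a read in the mCherry-positive libraries, against 15676 to 18795 in the YFP-positive and 18738 to 19810 in the negative libraries. Replicates also varied more in the mCherry-positive fraction, where the median standard deviation of a gene was 1.245 on the log2 scale, against 0.383 in the YFP-positive and 0.279 in the negative fraction. Transcripts of the mitochondrial genome took 6.59 to 7.86% of reads in the mCherry-positive, 9.18 to 14.5% in the YFP-positive and 5.73 to 7.46% in the negative libraries.

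**Figure D1:**
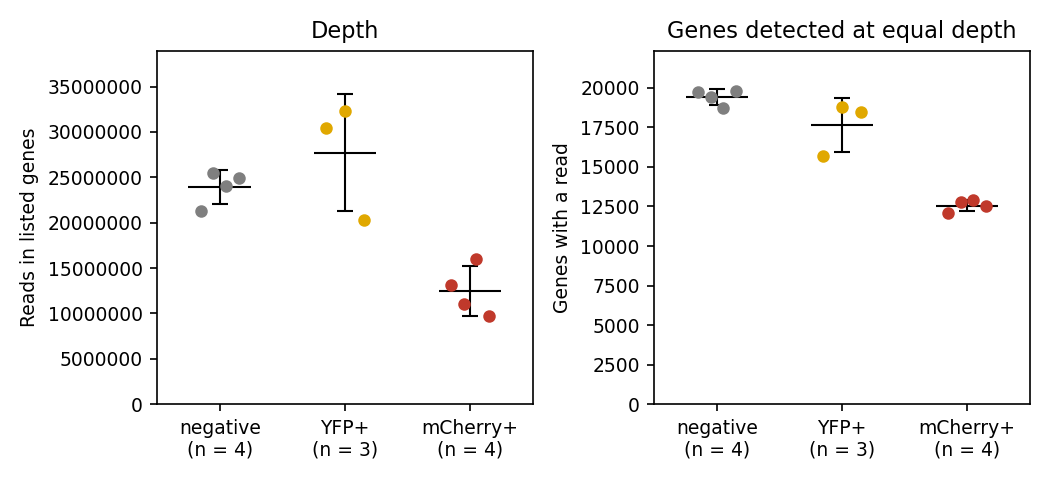
Reads in listed genes (left) and genes with a read after thinning to equal depth (right) per library in the negative (n = 4), YFP-positive (n = 3) and mCherry-positive (n = 4) fractions; points are libraries and bars are mean ± SD. At equal depth the 4 mCherry-positive libraries held 12069 to 12881 genes, below every other library.

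The first comparison asked what set cells with an active p16 reporter apart from the rest of the lung. Cdkn2a, the gene that encodes p16, was 35.8-fold higher in the mCherry-positive fraction, at 1423 ± 638 normalised reads (SD, n = 4) against 39.7 ± 4.03 in the negative fraction (n = 4), a log2 fold change of 4.96 ± 0.57 (SE, limma adjusted p = 8.81e-05). Its neighbour Cdkn2b, which encodes the inhibitor p15, rose by 3.48 ± 0.43 on the log2 scale, and Cdkn1a, which encodes p21, rose by 1.30 ± 0.15. Kras did not pass, at 1813 ± 346 and 1815 ± 253 normalised reads (log2 fold change -0.01 ± 0.20, adjusted p = 0.974), and the sign of this small value changed under several alternatives. On the mm10 build, Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 at 89274471 to 89294653, Cdkn2b (ENSMUSG00000073802) on chromosome 4 at 89306299 to 89311039, Cdkn1a (ENSMUSG00000023067) on chromosome 17 at 29090976 to 29100727 and Kras (ENSMUSG00000030265) on chromosome 6 at 145216699 to 145250239. Each value sums a whole gene, so transcripts of Cdkn2a that encode p16 and those that encode p19Arf could not be separated.

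**Figure D2:**
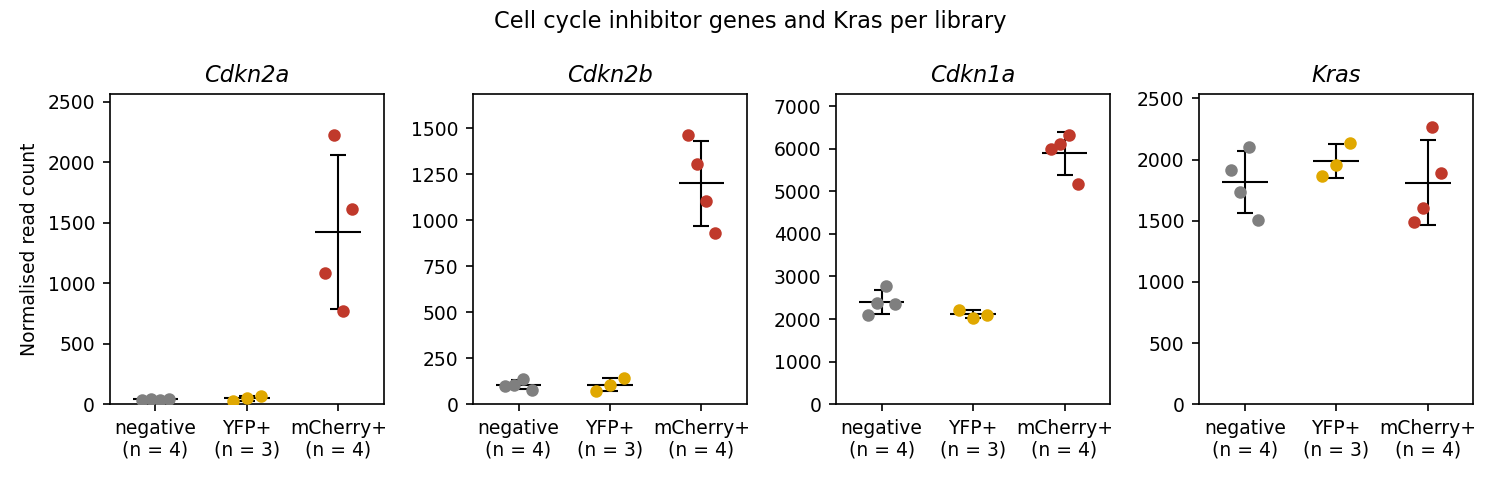
Normalised read counts of Cdkn2a, Cdkn2b, Cdkn1a and Kras per library in the negative (n = 4), YFP-positive (n = 3) and mCherry-positive (n = 4) fractions; points are libraries and bars are mean ± SD. Cdkn2a lay at 769 to 2223 in the mCherry-positive libraries and at 29.5 to 70.3 in all others.

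The list of arrest and senescence genes holds Cdkn2a, whose reporter set the mCherry gate, and its neighbour Cdkn2b. The rise of Cdkn2a is therefore tied to the sort, and the list was not tested without these genes. Of 18 tested genes of cell cycle arrest and senescence, 9 rose in the mCherry-positive fraction (9 adjusted over the list alone) and 1 fell (camera adjusted p = 1.4e-06, and adjusted p = 0.032 with an estimated correlation). Among them Serpine1, an inhibitor of plasminogen activators, rose by 2.68 ± 0.24 on the log2 scale, while Cdkn1c, another inhibitor gene, had a log2 fold change of -4.51 ± 1.44, a call that was lost without any single library other than mCherry-positive replicate 2 (adjusted p 0.0503 to 0.0824), with quantile normalization (0.107) and when only these 2 groups were fitted (0.077). Among 49 genes of factors secreted by senescent cells, 9 rose and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.5 with an estimated correlation). The median of that list was -0.02 and its mean -0.21, so both lay below 0 while the test, which compares a list with all other genes, gave a positive direction. Plau, the urokinase gene, rose by 3.24 ± 0.25, Igfbp7, which binds insulin-like growth factors, rose by 3.29 ± 0.27, and Vegfa, an endothelial growth factor, was lower (log2 fold change -1.79 ± 0.28). Genes of cell division went the other way, with 11 of 26 lower (13 adjusted over the list alone) and 1 higher (camera adjusted p = 0.035, and adjusted p = 0.5 with an estimated correlation). The checkpoint kinase gene Bub1 had no read in the mCherry-positive fraction and was at least 78.2-fold lower there, against a floor of 3 reads over the group. Such bounds cover counting error only. At equal depth, 3.98 to 7.46% of genes with at least 100 reads in 1 mCherry-positive library had 0 in another.

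Some genes of both alveolar and interstitial macrophages were higher. Of 20 alveolar macrophage genes 8 rose (8 adjusted over the list alone) and 1 fell (camera adjusted p = 7.9e-07, and adjusted p = 0.35 with an estimated correlation). Chil3, a secreted chitinase-like protein, rose by 3.01 ± 0.53, whereas Siglecf, a surface marker of alveolar macrophages, had a log2 fold change of -3.68 ± 1.07, a call lost without negative replicate 2, 3 or 4 (adjusted p 0.0539 to 0.0764), with quantile normalization (0.756) and with weights per library or per group (0.067 and 0.0682). Of 15 interstitial macrophage genes 4 rose and 0 fell (3 rose adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.5 with an estimated correlation), among them the chemokine gene Ccl8, 86.2-fold higher (log2 fold change 6.32 ± 1.04). Among 18 genes shared by macrophages only Mertk, a receptor for dying cells, passed, and it rose by 2.73 ± 0.28, alone also when adjusted over the list alone (camera adjusted p = 0.035, and adjusted p = 0.65 with an estimated correlation), while the median of the list was 0.08 and its mean 0.00. Lysosomal genes rose in 7 of 26 cases and fell in 0, with the same numbers adjusted over the list alone (camera adjusted p = 7.9e-07, and adjusted p = 0.26 with an estimated correlation). Lamp1, a membrane protein (log2 fold change 1.48 ± 0.11), and Grn, which encodes progranulin (1.74 ± 0.30), were among these. Pla2g2d, a secreted phospholipase, Fcna, a lectin, and Fabp1, a fatty acid carrier, were among the 5 largest rises with Ccl8 and Cdkn2a, with log2 fold changes of 6.72 ± 1.20, 6.67 ± 1.71 and 5.17 ± 0.97.

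Endothelial genes were higher as well, though not all of them. Of 18 tested, 11 rose (11 adjusted over the list alone) and 3 fell (4 adjusted over the list alone; camera adjusted p = 9.3e-06, and adjusted p = 0.5 with an estimated correlation). With quantile normalization 4 rose and 2 fell. Kdr, the main receptor for VEGF, stood at 64498 ± 26574 normalised reads against 6596 ± 838 (log2 fold change 3.21 ± 0.28), and the junction gene Esam rose by 1.78 ± 0.34, but Vwf, which encodes the clotting factor von Willebrand factor, was 9.32-fold lower (log2 fold change -3.88 ± 0.79). Car4, a carbonic anhydrase listed among alveolar macrophage genes and also a gene of lung capillaries, rose by 3.79 ± 0.27, and Emp2, a membrane protein listed for alveolar type 1 cells, rose by 3.06 ± 0.23. Of 14 alveolar type 1 genes 3 rose and 6 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.99). Of 14 club and ciliated cell genes 3 fell (0 adjusted over the list alone; camera adjusted p = 0.36, positive in direction with a median of -1.41), but without mCherry-positive replicate 1 5 rose, 0 fell and the list passed as higher (0.012), and with quantile normalization 2 rose, the median turned to 1.32 and the list passed (0.046). Scgb1a1, a secretory protein of club cells named after its values were seen, stood at 41068 to 143190 normalised reads in mCherry-positive replicates 2 to 4, 677.28 in replicate 1 and 4719.8 to 18729 in the negative libraries (log2 fold change 1.00 ± 1.31, adjusted p = 0.587, and 2.71 without replicate 1, 0.00327). It was 0.14 without mCherry-positive replicate 2 and 0.43 without replicate 3.

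Part of the genes of several other cell types were lower in the mCherry-positive fraction. Over all tested genes 3884 of 16362 fell and the median log2 fold change was -1.02, so the shares below are to be read against these. Neutrophil genes fell in 9 of 14 cases, with the same number adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.5 with an estimated correlation). The calcium-binding S100a8 (log2 fold change -6.79 ± 1.53) was one of these. Of 13 B and plasma cell genes 8 fell (10 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.5 with an estimated correlation). Ms4a1, which encodes CD20 (-4.17 ± 0.80), was one of these. Monocyte genes fell in 8 of 14 cases and rose in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.087). The chemokine receptor gene Ccr2 stood at -2.10 ± 0.49. Of 12 genes of antigen presentation by MHC class II, 8 fell (10 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.54 with an estimated correlation). H2-Eb1, a class II chain (-1.12 ± 0.28), was one of these. Mesenchymal genes fell in 8 of 20 cases (14 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.65 with an estimated correlation). The pericyte receptor gene Pdgfrb (-5.48 ± 1.30) was one of these. Alveolar type 2 genes fell in 4 of 18 cases, a share near that over all tested genes (3 adjusted over the list alone, and camera adjusted p = 0.26). The protease gene Napsa (-5.08 ± 1.00) was one of these. The 5 largest falls were those of Sell, a homing receptor of leukocytes (-8.98 ± 1.35), Klri2, a receptor of natural killer cells that had no read in the mCherry-positive fraction and was at least 598-fold lower, Tnfrsf13c, the BAFF receptor of B cells (-8.62 ± 1.02), Notch3, a receptor of mural cells (-8.34 ± 1.04), and Hhip, a hedgehog-binding protein (-8.27 ± 1.30).

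Lists of stress and signalling genes gave further differences. Of 18 early response and heat shock genes often induced when tissue is dissociated, 8 rose and 0 fell (11 rose adjusted over the list alone; camera adjusted p = 4.4e-08, and adjusted p = 0.26 with an estimated correlation). Ier2 (1.29 ± 0.20) was one of these. Mitochondrially encoded genes rose in 7 of 13 cases (8 adjusted over the list alone; camera adjusted p = 7.9e-07, and adjusted p = 0.42 with an estimated correlation). mt-Nd2, a complex I subunit (0.97 ± 0.20), was one of these. Among 18 genes that follow MAPK signalling 5 rose, with Spred2, a feedback inhibitor, at 1.73 ± 0.23, and 1 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.00064, and adjusted p = 0.26 with an estimated correlation), while the median of the list was -0.06 and its mean 0.28. Of 18 interferon response genes only Bst2, which encodes the antiviral protein tetherin, passed, at 1.31 ± 0.31, and no other passed when adjusted over the list alone (camera adjusted p = 0.00064, and adjusted p = 0.5 with an estimated correlation). Lipid genes were divided, 2 higher and 5 lower of 20 (2 and 8 adjusted over the list alone; camera adjusted p = 0.57, positive in direction with a median of -0.85). The fatty acid receptor gene Cd36 stood at 1.70 ± 0.18 and the desaturase gene Scd1 at -2.79 ± 0.54.

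In all, 4930 of 16362 tested genes passed an adjusted p of 0.05 in limma, 1046 higher and 3884 lower in the mCherry-positive fraction, and 1424 of the lower genes had no read there. In data simulated with the spread of each fraction, 368 of the genes left unchanged were called, 351 of them lower, so a wider spread in the mCherry-positive fraction adds lower calls. These false calls were 73.7% of all calls in that simulation, a share that depends on how many genes were changed there. The median log2 fold change of all tested genes was -1.02, which moved to -0.01 with quantile normalization, where 1440 genes were higher and 1280 lower (52.9% higher, against 21.2%), and to -1.29 with scaling to library totals. Measured against that median, the alveolar macrophage list stood 2.62 higher on the log2 scale, the endothelial list 2.83 higher, the senescence list 1.66 higher, the neutrophil list at -3.45 and the cell cycle list at -1.50. With quantile normalization the list calls ended for macrophage core genes (adjusted p = 0.79, with a median of -0.03), endothelial genes (0.069, with 4 members higher and 2 lower), secreted senescence factors (0.55, with a median of 0.13), lysosomal (0.083), interferon response (0.14), dissociation stress (0.81, with 1 member higher and 1 lower) and mitochondrially encoded genes (0.78, with 2 members higher and 1 lower), and the median of MAPK genes turned to 0.46. With weights per library or per group, which lowered the number of genes past the threshold to 1831 and 1825, the calls of Chil3, Fabp1, Ccl8, Siglecf, Ms4a1, H2-Eb1, Pdgfrb, mt-Nd2 and Bst2 were lost in at least 1 of these fits (adjusted p 0.0563 to 0.372). Scaling to library totals ended the calls of B and plasma cell (0.053) and cell cycle genes (0.055, and 0.071 with 2 groups alone), weights per library those of MHC class II (0.058) and mesenchymal genes (0.13), and a pseudocount of 0.5 that of B and plasma cell genes (0.056). Monocyte and alveolar type 2 lists passed with quantile normalization (9.1e-05 and 0.0062). Among genes with a mean of at least 1000, the calls of Fcna (0.435) and of the macrophage core (1), interstitial macrophage (0.56), endothelial (0.059), secreted factor (0.083), interferon (0.52) and MAPK lists (0.084) ended. Leaving out single libraries ended several list calls. These were macrophage core genes (without negative replicate 1 or 3 or mCherry-positive replicate 2, 3 or 4, adjusted p 0.05 to 0.3), B and plasma cell genes (negative replicate 1 or mCherry-positive replicate 3, 0.06 and 0.086), cell cycle genes (negative replicate 1 or 3, YFP-positive replicate 1 or mCherry-positive replicate 1, 0.052 to 0.12), MHC class II genes (negative replicate 3 or mCherry-positive replicate 1 or 4, 0.055 to 0.093) and mesenchymal genes (negative replicate 3 or mCherry-positive replicate 2, 0.064 and 0.1). The number of members past the threshold fell by over 1.5 times without negative replicate 1 for neutrophil (4), B and plasma cell (5), cell cycle (4) and dissociation stress genes (4), without negative replicate 2 for monocyte (5) and mitochondrially encoded genes (3), and without negative replicate 3 for mesenchymal (1), MHC class II (2) and alveolar type 2 genes (2). Alveolar type 2 genes that fell came to 7 without negative replicate 1, where that list passed as lower (0.034), and the monocyte list passed as lower without mCherry-positive replicate 4 (0.046). Without negative replicate 1 the count was 2 for interstitial macrophage genes that rose and 3 for alveolar type 1 genes that fell, and without mCherry-positive replicate 1 it was 17 for secreted senescence factors, 5 for interferon response genes and 5 for macrophage core genes that rose.

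**Figure D3:**
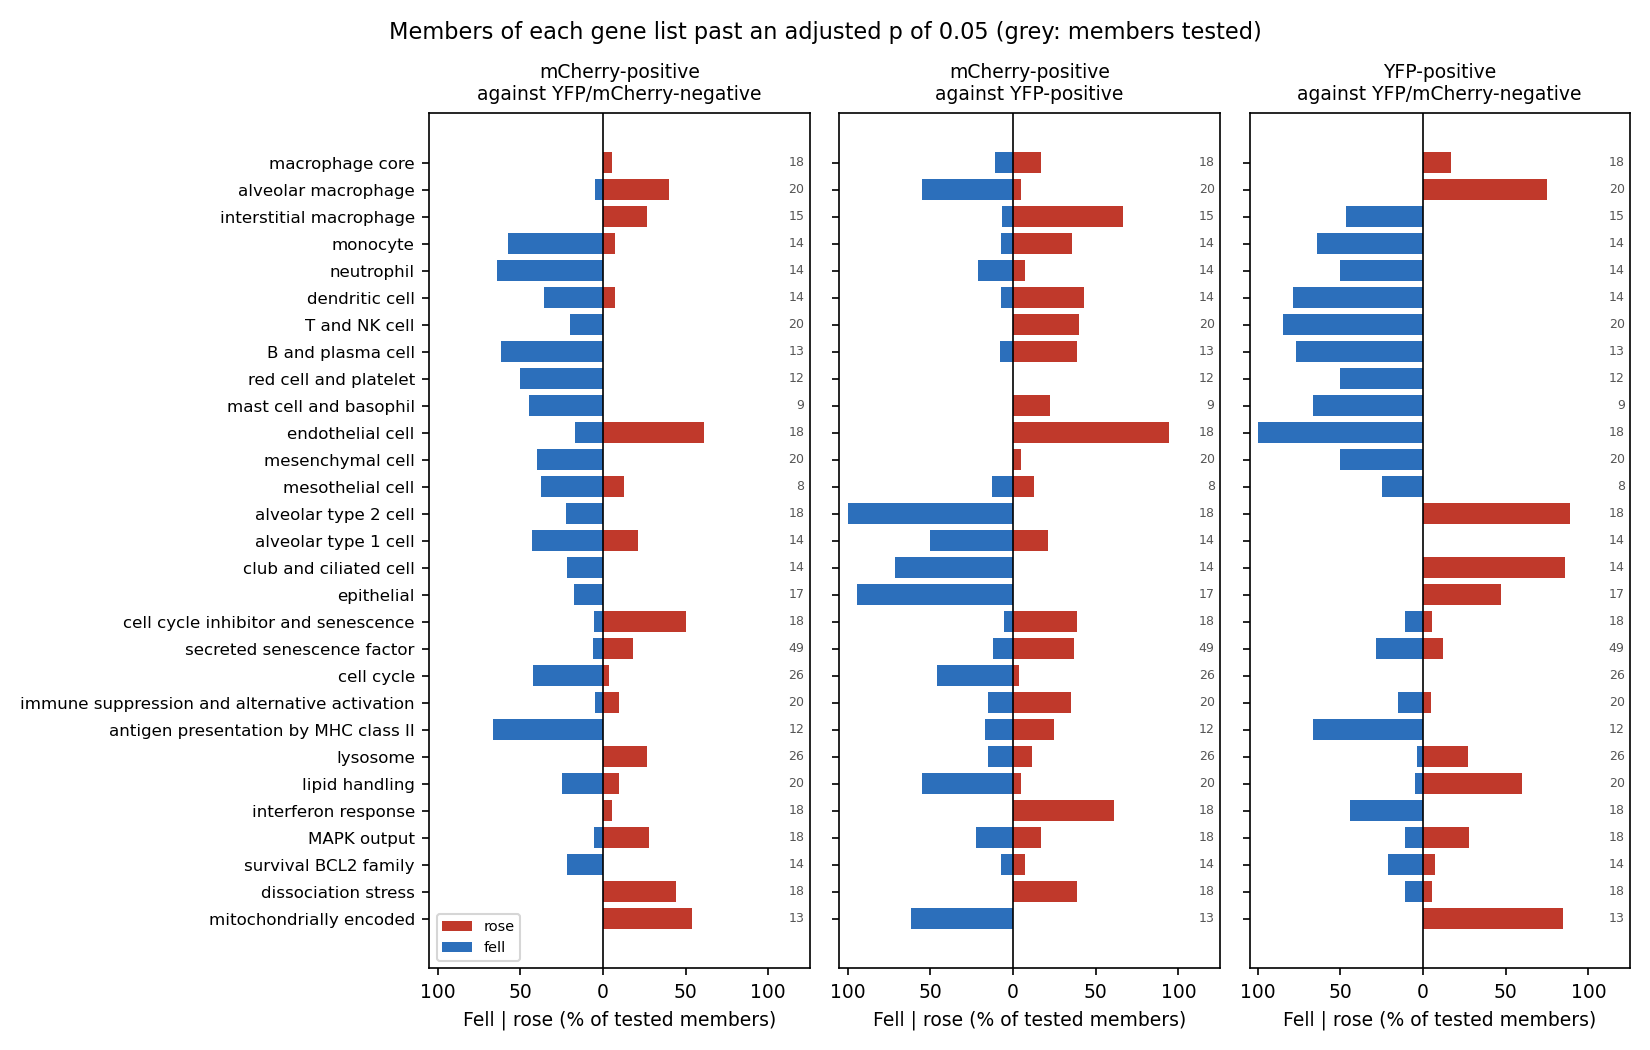
Share of the tested members of each of 29 gene lists (%, horizontal axis) that rose (red, right) or fell (blue, left) at a limma adjusted p of 0.05 in each of the 3 comparisons; grey numbers give the members tested. Endothelial genes rose in 11 of 18 cases against the negative fraction and in 17 of 18 against the YFP-positive fraction.

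The second comparison set cells with an active p16 reporter against the sorted tumour cells. Cdkn2a was 28.5-fold higher in the mCherry-positive (n = 4) than in the YFP-positive fraction (n = 3), where it stood at 49.9 ± 20.4 normalised reads (log2 fold change 4.72 ± 0.61, SE, limma adjusted p = 9.89e-05). Cdkn2b rose by 3.50 ± 0.47, Cdkn1a by 1.48 ± 0.16 and Serpine1 by 2.70 ± 0.26, while Kras had a log2 fold change of -0.15 ± 0.21 (adjusted p = 0.627). The 5 largest rises were those of Apln, which encodes the vascular peptide apelin (10.20 ± 0.89), Ccl8, with no read in the YFP-positive fraction and at least 2310.0-fold higher, Tmeff2, a transmembrane protein with follistatin domains (9.58 ± 0.80), Fibin (9.41 ± 0.56) and Jchain, the joining chain of antibodies (9.28 ± 0.68). Among the 5 largest falls were Egfl6, listed for alveolar type 2 cells (-9.73 ± 1.43), Lgi3 (-10.44 ± 1.18) and Arhgap44, which had no read in the mCherry-positive fraction and was at least 1110.0-fold lower.

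Most genes of the lung epithelium were lower. All 18 tested alveolar type 2 genes fell, as they did adjusted over the list alone (camera adjusted p = 1.8e-07, and adjusted p = 0.23 with an estimated correlation). Slc34a2, a phosphate transporter, was 407-fold lower (log2 fold change -9.03 ± 1.08) and the chemokine gene Cxcl15 stood at -8.76 ± 1.19. Of 17 general epithelial genes 16 fell, the same number as adjusted over the list alone (camera adjusted p = 7.5e-05, and adjusted p = 0.23 with an estimated correlation). The surface antigen gene Tacstd2 (-8.79 ± 0.90) was one of these. Of 14 club and ciliated cell genes 10 fell (11 adjusted over the list alone; camera adjusted p = 0.00054, and adjusted p = 0.25 with an estimated correlation). Hp, which encodes haptoglobin (-6.64 ± 0.75), was one of these. Alveolar type 1 genes were divided, with 3 higher, such as Emp2 (2.92 ± 0.25), and 7 lower, such as the proteoglycan gene Spock2 (-3.78 ± 0.60), out of 14 (3 and 10 adjusted over the list alone; camera adjusted p = 0.56). Lipid handling genes fell in 11 of 20 cases and rose in 1 (13 and 2 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.2 with an estimated correlation). Scd1 stood at -6.32 ± 0.59 and the fatty acid synthase gene Fasn at -4.94 ± 0.40.

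Endothelial genes were higher in 17 of 18 cases, also adjusted over the list alone (camera adjusted p = 1.5e-19, and adjusted p = 0.2 with an estimated correlation). Kdr was 32.3-fold higher (log2 fold change 4.99 ± 0.30) and Calcrl, a receptor for adrenomedullin, stood at 75877 ± 24467 normalised reads against 1330.3 ± 1128 (6.12 ± 0.44). Interstitial macrophage genes rose in 10 of 15 cases and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 5.3e-06, and adjusted p = 0.23 with an estimated correlation). The scavenger receptor genes Stab1 (8.07 ± 1.07) and Lyve1 (6.91 ± 0.95) were among these. Alveolar macrophage genes went the other way, with 11 of 20 lower and 1, Car4 (3.74 ± 0.29), higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.034, and adjusted p = 0.53 with an estimated correlation). Siglecf was 136-fold lower (log2 fold change -7.78 ± 1.15) and Plet1, also on the alveolar macrophage list, was lower by 6.97-fold (-2.91 ± 0.55). Macrophage core genes were split between 3 higher and 2 lower of 18, with the same numbers adjusted over the list alone (camera adjusted p = 0.076).

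Some lymphoid genes were higher than in the tumour cell fraction. T and NK cell genes rose in 8 of 20 cases, the same number as adjusted over the list alone (camera adjusted p = 1.2e-07, and adjusted p = 0.23 with an estimated correlation). The granzyme gene Gzmb (7.11 ± 0.84) and the T cell receptor component gene Cd3e (5.63 ± 0.85) were among these. Of 13 B and plasma cell genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00013, and adjusted p = 0.23 with an estimated correlation). Of 14 dendritic cell genes 6 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.23 with an estimated correlation). The transcription factor gene Zbtb46 stood at 4.13 ± 0.30. Of 14 monocyte genes 5 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 0.0091, and adjusted p = 0.24 with an estimated correlation). Of 20 mesenchymal genes 1 rose (0 adjusted over the list alone; camera adjusted p = 0.0091, and adjusted p = 0.53 with an estimated correlation). Among 9 mast cell and basophil genes 2 rose, the same number as adjusted over the list alone (camera adjusted p = 0.0091, and adjusted p = 0.23 with an estimated correlation). Gata2 (7.82 ± 0.90), a transcription factor that endothelial cells also use, was one of these.

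In both senescence lists more genes rose than fell. Of 18 genes of arrest and senescence 7 rose and 1 fell, the same as adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.062 with an estimated correlation). This list again holds Cdkn2a, the gene behind the mCherry gate, and Cdkn2b. Of 49 secreted factors 18 rose and 6 fell (19 and 7 adjusted over the list alone; camera adjusted p = 3.9e-06, and adjusted p = 0.25 with an estimated correlation). Igfbp7 rose by 4.67 ± 0.30 and Plau by 4.29 ± 0.27, while the chemokine gene Ccl20 had no read in the mCherry-positive fraction and was at least 89.4-fold lower, and Spp1, which encodes osteopontin, was at -2.91 ± 0.54. Cell division genes fell in 12 of 26 cases and rose in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 0.0091, and adjusted p = 0.32 with an estimated correlation). Bub1 had no read in the mCherry-positive fraction and was at least 323-fold lower. Interferon response genes rose in 11 of 18 cases, also adjusted over the list alone (camera adjusted p = 9.6e-09, and adjusted p = 0.2 with an estimated correlation). Bst2 (2.70 ± 0.34) and Oasl2 (2.00 ± 0.33) were among these. Among 20 genes of immune suppression and alternative activation 7 rose and 3 fell, the same as adjusted over the list alone (camera adjusted p = 0.0029, and adjusted p = 0.24 with an estimated correlation). Il10, an anti-inflammatory cytokine gene, stood at 7.05 ± 1.12 and the interleukin 4 receptor gene Il4ra at 1.91 ± 0.26.

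The MAPK list held members that went both ways, 3 higher, such as the early response gene Ier3 (3.14 ± 0.22), and 4 lower of 18, as adjusted over the list alone (camera adjusted p = 0.64, positive in direction while the median was -0.57). Etv4, a transcription factor downstream of this pathway, had no read in the mCherry-positive fraction and was at least 98.7-fold lower. Lysosomal genes were likewise divided, with 3 higher and 4 lower of 26, as adjusted over the list alone (camera adjusted p = 0.35, positive in direction with a median of -0.18), among the latter the cholesterol carrier gene Npc2 (-2.17 ± 0.35). Dissociation stress genes rose in 7 of 18 cases, also adjusted over the list alone (camera adjusted p = 3.8e-05, and adjusted p = 0.23 with an estimated correlation). The phosphatase gene Dusp1 (1.34 ± 0.17) was one of these. Mitochondrially encoded genes fell in 8 of 13 (9 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). mt-Nd5 (-1.24 ± 0.23) was one of these.

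In limma 5267 of 16362 genes passed, 1468 higher and 3799 lower in the mCherry-positive fraction, and 1194 of the lower genes had no read there. The median log2 fold change of all tested genes was -0.85, and with quantile normalization, which brought it to -0.02, 49.2% of the calls were higher against 27.9%. Above that median stood the endothelial list by 7.44 and the interstitial macrophage list by 5.90, and the alveolar type 2 list lay at -6.62 from it. The call of the dissociation stress list ended with quantile normalization (adjusted p = 0.47, with 4 members higher and 1 lower), that of alveolar macrophage genes with a pseudocount of 0.5 (0.051) or weights per group (0.06), that of mitochondrially encoded genes with weights per library or per group (0.29 and 0.16), and that of Plet1 with weights per library or per group (0.134 and 0.165). Among genes with a mean of at least 1000, the interstitial macrophage (0.26), monocyte (0.1), dendritic cell (0.12), mesenchymal (0.48), immune suppression (0.12), interferon (0.08) and dissociation stress calls (0.12) ended. Without single libraries the list calls of alveolar macrophage genes (YFP-positive unnumbered or mCherry-positive replicate 1 or 4, adjusted p 0.052 to 0.057) and mitochondrially encoded genes (YFP-positive replicate 1 or mCherry-positive replicate 1, 0.05 and 0.052) ended, and so did that of mesenchymal genes (YFP-positive replicate 1, 0.16, with 0 members past the threshold), whose median turned to -0.05 with weights per library. Mesenchymal genes that rose came to 6 without YFP-positive replicate 2, where 1 MAPK gene fell, and without mCherry-positive replicate 2 8 lysosomal genes fell. The number of alveolar macrophage genes that fell dropped to 5 without YFP-positive replicate 2, of epithelial genes to 10 and of B and plasma cell genes that rose to 3 without YFP-positive replicate 1, and of cell cycle genes that fell to 7 without the unnumbered YFP-positive library. T and NK cell genes that rose came to 14 without mCherry-positive replicate 3 and macrophage core genes that rose to 0 without YFP-positive replicate 1 and to 8 without mCherry-positive replicate 1, where that list passed as higher (0.00049), as it did with no filter on low values (0.037).

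A set of 666 genes was higher in the mCherry-positive fraction than in both others, and 2261 were lower than in both. Independent lists of these sizes share 94 and 902 genes. Both comparisons use the same mCherry-positive libraries. In 50 simulations with no difference between fractions, 12.62 genes were higher than in both on average, and at most 29. The same simulations gave 7.02 lower genes on average and at most 18. Counts simulated with each fraction's own spread gave 351 unchanged genes called lower against the negative and 281 against the YFP-positive fraction. How many of these were lower than in both was not counted, so 7.02 may understate the lower genes expected with no difference. With the mCherry-positive libraries split so that each comparison used its own pair, 608 to 711 genes were higher and 1896 to 2134 lower in both over the 6 splits. Cdkn2a, Cdkn2b, Cdkn1a, Serpine1, Plau, Igfbp7, Kdr, Car4, Emp2, Ccl8 and Bst2 were among the genes higher in both.

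The third comparison set the sorted tumour cells against the rest of the lung. Among the 5 largest rises in the YFP-positive fraction (n = 3) over the negative fraction (n = 4) was that of Cyp2f2, a cytochrome of club cells, which stood at 98941 ± 34722 normalised reads (SD) against 617 ± 361, a log2 fold change of 7.62 ± 1.61 (SE, limma adjusted p = 0.00538), and Gabrp, a subunit of a GABA receptor, Muc5b, a secreted mucin, and Acaa1b, a peroxisomal thiolase, had log2 fold changes of 8.12 ± 1.43, 8.07 ± 1.63 and 7.68 ± 1.57. Among the 5 largest falls were Cd79a, a part of the B cell receptor (-7.91 ± 1.41), Jchain (-7.91 ± 0.68) and Ms4a6b, a leukocyte membrane protein (-7.49 ± 0.68). Kras and the inhibitor genes did not pass, with log2 fold changes of 0.14 ± 0.21 for Kras, 0.24 ± 0.61 for Cdkn2a, -0.02 ± 0.47 for Cdkn2b and -0.18 ± 0.16 for Cdkn1a, and the first 3 changed sign under some alternatives, while Cdkn1a came past the threshold with scaling to library totals (-0.5, adjusted p = 0.0473).

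Of 18 alveolar type 2 genes 16 rose (17 adjusted over the list alone; camera adjusted p = 1.3e-10, and adjusted p = 0.12 with an estimated correlation). The lipid transporter gene Abca3 (3.95 ± 0.55), Slc34a2 (6.28 ± 1.08) and the lung transcription factor gene Nkx2-1 (3.94 ± 0.76) were among these. Club and ciliated cell genes rose in 12 of 14 cases (14 adjusted over the list alone; camera adjusted p = 7e-09, and adjusted p = 0.099 with an estimated correlation). Hp (4.96 ± 0.75) and Ccdc153, a gene of ciliated cells (6.01 ± 0.89), were among these. Of 17 general epithelial genes 8 rose (14 adjusted over the list alone; camera adjusted p = 5.4e-07, and adjusted p = 0.12 with an estimated correlation). Cdh1, which encodes E-cadherin (4.15 ± 0.75), was one of these. Hnf4a, a transcription factor of gut and liver epithelium, had reads in the YFP-positive fraction only and was at least 91.9-fold higher. No alveolar type 1 gene of 14 passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.48), while 1 had an unadjusted p under the threshold and 3 rose with voom. Lipid handling genes rose in 12 of 20 cases and fell in 1, the same as adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.031 with an estimated correlation). Fasn stood at 3.54 ± 0.40, Scd1 at 3.53 ± 0.59 and Dgat1, which makes triglycerides, at -2.44 ± 0.51.

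Alveolar macrophage genes rose with the epithelial ones, in 15 of 20 cases (16 adjusted over the list alone; camera adjusted p = 5.6e-11, and adjusted p = 0.095 with an estimated correlation). Chil3 stood at 41629.9 ± 11562 normalised reads against 1122 ± 639.8 (log2 fold change 5.37 ± 0.57) and Plet1 at 4.98 ± 0.55. Macrophage core genes rose in 3 of 18 cases, the same number as adjusted over the list alone (camera adjusted p = 0.92, positive in direction with a median of -0.48). Mertk stood at 2.10 ± 0.30. Lysosomal genes rose in 7 of 26 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.19 with an estimated correlation). Npc2 stood at 2.17 ± 0.35. Interstitial macrophage genes fell in 7 of 15 cases, also adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.43 with an estimated correlation). Lyve1 (-5.81 ± 0.95) was one of these. Mitochondrially encoded genes rose in 11 of 13 cases, also adjusted over the list alone (camera adjusted p = 4.2e-10, and adjusted p = 0.12 with an estimated correlation). mt-Nd2 (1.83 ± 0.22) was one of these.

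Endothelial genes fell, and so did part of the genes of other cell types. All 18 endothelial genes were lower, also adjusted over the list alone (camera adjusted p = 1.7e-15, and adjusted p = 0.1 with an estimated correlation). Calcrl was 18.9-fold and the adhesion gene Pecam1 21.7-fold lower (log2 fold changes -4.58 ± 0.44 and -4.95 ± 0.54). T and NK cell genes fell in 17 of 20 cases (19 adjusted over the list alone; camera adjusted p = 2e-11, and adjusted p = 0.095 with an estimated correlation). The interleukin 7 receptor gene Il7r stood at -5.60 ± 0.40 and Cd3e at -6.49 ± 0.85. B and plasma cell genes fell in 10 of 13 (12 adjusted over the list alone; camera adjusted p = 5.3e-09, and adjusted p = 0.088 with an estimated correlation). Ms4a1 stood at -7.10 ± 0.86. Dendritic cell genes fell in 11 of 14 cases (13 adjusted over the list alone; camera adjusted p = 1e-07, and adjusted p = 0.095 with an estimated correlation). The homing receptor gene Ccr7 stood at -6.47 ± 0.48. Monocyte genes fell in 9 of 14 (9 adjusted over the list alone; camera adjusted p = 9.1e-07, and adjusted p = 0.088 with an estimated correlation). Ccr2 stood at -5.14 ± 0.53. Neutrophil genes fell in 7 of 14 (10 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0052, and adjusted p = 0.36 with an estimated correlation). The protease gene Mmp9 stood at -5.85 ± 0.80. Mast cell and basophil genes fell in 6 of 9 cases (7 adjusted over the list alone; camera adjusted p = 4.2e-06, and adjusted p = 0.044 with an estimated correlation). Gata2 stood at -5.58 ± 0.90. Red cell and platelet genes fell in 6 of 12 (7 adjusted over the list alone; camera adjusted p = 0.00012, and adjusted p = 0.2 with an estimated correlation). Mesenchymal genes fell in 10 of 20 (16 adjusted over the list alone; camera adjusted p = 5.4e-07, and adjusted p = 0.2 with an estimated correlation). Of 8 mesothelial genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.12). The caveolar gene Cav1 stood at -1.84 ± 0.26. Genes of antigen presentation by MHC class II fell in 8 of 12 cases (9 adjusted over the list alone; camera adjusted p = 3.3e-05, and adjusted p = 0.19 with an estimated correlation). H2-Eb1 stood at -2.58 ± 0.30.

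MAPK output genes rose in 5 of 18 cases and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0098, and adjusted p = 0.19 with an estimated correlation). Cyclin D1, Ccnd1, stood at 2.70 ± 0.41 and Ier3 at -2.00 ± 0.22. Of 18 genes of arrest and senescence 1, the stress cytokine gene Gdf15 (2.81 ± 0.59), rose and 2 fell, among them the death receptor gene Tnfrsf10b (-1.91 ± 0.31), with 1 and 1 adjusted over the list alone (camera adjusted p = 0.68). Secreted senescence factors fell in 14 of 49 cases and rose in 6 (18 and 6 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation). The chemokine gene Ccl5 stood at -4.79 ± 0.47 and the cytokine gene Il1a at 3.29 ± 0.67. Of 20 genes of immune suppression and alternative activation 1, Gpnmb (3.55 ± 0.59), rose and 3 fell, such as Il4ra (-1.69 ± 0.26), with 2 and 7 adjusted over the list alone (camera adjusted p = 0.14). Interferon response genes fell in 8 of 18 cases (11 adjusted over the list alone; camera adjusted p = 7.8e-05, and adjusted p = 0.2 with an estimated correlation). Gbp3 (-2.40 ± 0.30) was one of these. No cell cycle gene of 26 passed in limma (camera adjusted p = 0.14), while 2 had an unadjusted p under the threshold and 2 rose with voom. With weights per library 15 rose and 2 fell, and with these 2 groups alone 10 rose and 2 fell. The main fit pools in the wide spread of the mCherry-positive libraries, so cell cycle genes are not shown to be unchanged. The proliferation marker gene Mki67 stood at 4448 ± 1165 against 2885 ± 973 normalised reads (log2 fold change 0.66 ± 0.72, adjusted p = 0.662) and passed with weights per library (0.94, adjusted p = 0.017). Among 14 genes of the BCL2 survival family 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.68). Among 18 dissociation stress genes 1 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.68).

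In this comparison 3347 genes passed in limma, 1493 higher and 1854 lower in the YFP-positive fraction, and the median log2 fold change was -0.02. Scaling to library totals moved that median to -0.33 and the share of higher calls from 44.6% to 32.5%, and turned the median of the dissociation stress list from 0.18 to -0.14. The number of genes past the threshold was 1890 without YFP-positive replicate 1 and 2109 without the unnumbered YFP-positive library. It was 8241 when only these 2 groups were fitted. The main fit shares 1 spread over all 3 fractions, so SEs and p-values here also carry the spread of the mCherry-positive libraries. The median SD of a gene was 1.245 there, against 0.383 in the YFP-positive and 0.279 in the negative fraction. Genes that did not pass in this comparison are therefore not shown to be unchanged. The secreted factor call ended with voom (adjusted p = 0.066), and among genes with a mean of at least 1000 the interstitial macrophage (0.31), neutrophil (0.68), secreted factor (0.28), interferon (0.097) and MAPK calls (0.088) ended. The cell cycle list passed, higher in direction, with 2 groups alone (0.028) or weights per library (0.0063). The MAPK list call ended without YFP-positive replicate 1 (0.055), and without that library the members past the threshold fell to 1 for epithelial, 9 for alveolar type 2, 5 for monocyte and for mesenchymal, 6 for dendritic cell, 10 for T and NK cell and 2 for red cell and platelet genes, while without the unnumbered library they fell to 3 for neutrophil and 4 for interferon response genes, and without negative replicate 2 or 3 to 5 for MHC class II genes and to 8 for secreted factors. MAPK genes that rose came to 3 without YFP-positive replicate 1 and to 8 without mCherry-positive replicate 1, immune suppression genes that fell to 6 without mCherry-positive replicate 1, and BCL2 family genes that fell to 0 without YFP-positive replicate 1. Epithelial genes that rose came to 13 without mCherry-positive replicate 1, and the mesothelial list passed as lower without negative replicate 1 (0.016). Arrest and senescence genes that fell came to 1 without negative replicate 1 and 3 without mCherry-positive replicate 4, and with weights per library 3 rose, 6 fell and the median turned from -0.02 to 0.2.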

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

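Of the tests reported in this part, those of sequencing depth, of both explanations for the alveolar macrophage genes and of carry-over for the endothelial genes were chosen after the result was seen.

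For 227 sets of 4 libraries, covering 112 named genes and 5 measures per library (reads, genes detected, the same at equal depth, the share of the 10 highest genes and the mitochondrial share), the gap of the highest or lowest library to its nearest neighbour was divided by the range, and 18 exceeded the 95% critical value of Dixon's test, where chance gives about 1 in 20. For 4 of them, Pla2g2d, Etv4, Hhip and Tnfrsf13c, a single library had reads, which sets the gap share to 1 whatever their number, so that chance rate does not apply and they tell nothing about the library. Gap shares of genes were computed on the deposited log2 values, while the reads printed here are on the linear scale. In negative replicate 1, Car4 (1930 normalised reads against 1250 to 1340, gap share 0.835) and Dgat1 (3330 against 1820 to 2010, 0.831) were high, Cyp2f2 was low (112 against 691 to 970, 0.842), and mitochondrial transcripts took 7.46% of reads against 5.73 to 5.92% (0.886). In negative replicate 4, Pla2g2d (2.52 normalised reads) and Etv4 (0.63) had reads while the others had 0 (gap share 1). In mCherry-positive replicate 1, Car4 (30000.0 against 17000.0 to 17900.0, 0.909), Ednrb (52100.0 against 31300.0 to 33100.0, 0.888) and Ier2 (8330.0 against 4620.0 to 4640.0, 0.992) were high, and Gabrp (3.11 against 511 to 730.0, 0.927) and Gdf15 (554 against 3050.0 to 3670.0, 0.902) were low. In mCherry-positive replicate 2, Vegfa (3420.0 against 1330.0 to 1460.0, 0.904), Hhip (22.7 against 0, 1) and mt-Nd5 (124000.0 against 73200.0 to 80000.0, 0.833) were high. In mCherry-positive replicate 3, H2-Eb1 (10200.0 against 6090.0 to 6400.0, 0.9), Tnfrsf10b (3220.0 against 1720.0 to 1870.0, 0.864) and Cxcl12 (1040.0 against 324 to 347, 0.941) were high, and in mCherry-positive replicate 4 Tnfrsf13c was high (11.7 against 0, 1).

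Few genes were detected in the mCherry-positive libraries. Lower depth alone is argued against, as at equal depth the highest mCherry-positive library held 12881 genes and the lowest other library 15676. A narrower mixture of cell types as the only cause, with the same genes wholly lost from all mCherry-positive libraries, is argued against. Of 10671 genes with a mean of at least 100 in the negative libraries, 1852 were at 0 in at least 1 mCherry-positive library. Only 93 of these (5.02%) were at 0 in all 4. A shared narrower mixture that left a few reads of a gene could give 0 in only some libraries, so this count cannot argue against it. A mixture that differed between the libraries could also give this result and was not tested. Little starting RNA or few cells may contribute, as between pairs of mCherry-positive libraries at least 3.98% and at most 7.46% of genes with 100 reads in one had 0 in the other, against at most 0.241% in YFP-positive and 0.0219% in negative pairs. The labels give no cell numbers, and a biological loss of transcripts in cells with an active p16 reporter was not tested.

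Alveolar macrophage genes were high in the YFP-positive fraction, described in the labels as tumour cells. Carry-over of negative-fraction cells is argued against by a median YFP-positive to negative ratio of 17.3 (lower quartile 7.16) for these genes, against 0.018 (upper quartile 0.0314) for T, NK and B cell genes. Macrophages inside the YFP gate could contribute, as macrophage core genes had a median ratio of 0.77, against an upper quartile of 0.0534 for lymphoid and endothelial genes. Whether such cells carried recombined YFP or were autofluorescent, and whether tumour cells used some of these genes, was not tested.

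Endothelial genes were high in the mCherry-positive fraction. Carry-over of negative-fraction cells is argued against, since 13 of 18 genes were higher in every mCherry-positive than in every negative library. The median ratio of the list was 3.88. Chance alone would give 1.43% per gene, but over all tested genes 30.1% did not overlap, in 1 direction or the other. The 1.43% is therefore not the background here. Size-factor scaling as the whole cause was tested with scaling to library totals, where 9 of 11 genes still rose. That scaling moved the median of all genes only from -1.02 to -1.29, a small shift beside the list median of 1.81. It could hardly have ended these calls, so it cannot decide the question. With quantile normalization only 4 rose and the list had a camera adjusted p of 0.069. The list median was then 1.36 (quartiles -0.83 and 1.79) against 1.81 (-0.68 and 2.13) before, while the median of all genes, against which the list is tested, moved from -1.02 to -0.01. Endothelial cells with an active p16 reporter, taken into a gate that names no lineage, remain a candidate explanation.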

How the results depend on the processing

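Library totals, equal depth, voom, weights per group, log2(value + 1) and the minimum mean of 1000 were chosen after the results were seen. Over 150 named gene results, 15 other alternatives and 11 left-out libraries, 3764 values kept their direction and side of the threshold, 65 were no longer past it, 5 came past it, 13 changed sign and 53 were missing because the gene was then not tested. The cause was not tested except where stated. Cdkn2a between YFP-positive and negative cells went to -0.14 with the replicate block, -0.06 with library totals and -0.04 to 0.55 with a library left out (lowest without the unnumbered YFP-positive library). Cdkn2b went to 0.29 with weights per library, 0.12 without negative replicate 3 and 0.22 without YFP-positive replicate 1, with a range of -0.26 to 0.22 over left-out libraries. Kras against the negative fraction went to -0.18 in YFP-positive cells with library totals, and in mCherry-positive cells to 0.07 with weights per library, 0.02 with voom and 0.02, 0.06, 0.08 and 0.04 without negative replicate 1 or 3 or mCherry-positive replicate 1 or 2 (-0.12 to 0.08 over all left-out libraries).

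The 4930 genes between mCherry-positive and negative cells became 3095 with a minimum of 50 (31.3% higher), 2720 with quantile normalization (1781 shared in direction, 40 reversed), 1831 with weights per library, 1825 with weights per group and 1173 at a mean of at least 1000 (63.9% higher), where fewer genes were tested, and 3426 to 5749 with a library left out. The 5267 against YFP-positive cells became 3430 with 2 groups alone and 1489 at a mean of at least 1000 (65.6% higher), and 3512 to 5909 with a library left out. The 3347 between YFP-positive and negative cells became 8241 with 2 groups alone, 9003 with weights per library, 7508 with weights per group, 1273 at a mean of at least 1000, and 1890 to 4055 with a library left out. Weights and fits without the mCherry-positive libraries give less room to their wide spread. Lists past the threshold numbered 18, 20 and 21 in these comparisons, 10, 9 and 12 at a mean of at least 1000, 1, 0 and 2 with an estimated correlation, and 14 to 18, 18 to 20 and 20 to 22 with a library left out. The 666 genes higher than in both became 248 with weights per library, 244 with weights per group and 512 to 831 with a library left out.

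Deviations of same-numbered libraries correlated at 0.141, 0.006, 0.115 and 0.015 between mCherry-positive and negative cells, 0.014 and -0.047 between mCherry-positive and YFP-positive cells, and 0.053 and 0.119 between YFP-positive and negative cells. In 5 of the 8 pairs, though not in all, this was higher than with any other number. The unnumbered YFP-positive library formed no pair. Not every pair exceeded 0.1 and the labels name no shared animal, so the numbers were not read as pairs. Pairing is not excluded by this. With the replicate block 3923, 3283 and 1825 genes passed and 408 were higher than in both. In that fit the unnumbered YFP-positive library had a block of its own and added nothing to the comparisons. Those with YFP-positive cells then rested on the other YFP-positive libraries, so the lower counts cannot be put down to pairing alone. Between mCherry-positive and negative cells the block ended the limma calls of Cdkn1c (adjusted p = 0.0674), Siglecf (0.0625) and Sema3c, named below (0.0654). It also ended the camera calls of mesenchymal genes between mCherry-positive and YFP-positive cells (0.071) and of secreted factors between YFP-positive and negative cells (0.063). With it the MHC class II list passed as higher between mCherry-positive and YFP-positive cells (0.045). The count tests planned for tables of counts were not run because the values are on a log2 scale. Of 35 splits of the libraries per comparison, the real one alone gave as many as 4930 (highest other 0), 5267 (3258) and 3347 genes (28). Of 100 regroupings, only the real one, 1 in all, was as large as the 666 (highest other 0). Other splits mix the sorted fractions, which widens the spread within groups and can lower these counts. A share of 1 in 35 is also the smallest these splits can give, so they cannot exclude chance on their own. For lists, 3, 1 and 13 of 35 splits, the real one included, gave as many as 18 (highest other 19), 20 (19) and 21 (23). Chance therefore cannot be excluded for 18 and 21, and for 20 the highest other split came close. Depth limits genes with few reads, above all in the mCherry-positive libraries.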

Other observations

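The test of lung capillary types was planned before its result was seen, but Car4 was left out of it afterwards, and no other test is reported in this part.

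Endothelial cells of the lung include capillary cells called aerocytes, which line the gas exchange surface, and general capillary cells, and markers of these and other vessel types were listed before the values of all but Car4 were looked up. All 9 aerocyte genes rose in the mCherry-positive fraction (n = 4) over the negative fraction (n = 4), with a median log2 fold change of 3.18, among them Ednrb, an endothelin receptor, at 37215 ± 9922 normalised reads (SD) against 2634 ± 329 (log2 fold change 3.79 ± 0.45), Prx at 16822 ± 5725 against 1810.2 ± 312, Kitl, the ligand of the receptor Kit, at 33505 ± 8548 against 4673 ± 433, and Chst1, Rprml, Cyp4b1, Pmp22 and Nckap5 at log2 fold changes of 3.70, 4.64, 2.81, 2.55 and 0.86. The ninth, Car4, is also on the alveolar macrophage list, so its rise was already reported and it was left out of the test below. With weights per library or per group the calls of Chst1 (adjusted p = 0.0678 and 0.0627) and Nckap5 (0.0704 and 0.0653) were lost, and with weights per group that of Rprml (0.0661). Of 6 general capillary genes 0 rose and 4 fell (median -2.12), with Aplnr, the apelin receptor, at 69.5 ± 105 against 761 ± 32.2 (-5.09 ± 1.38) and Gpihbp1 at a log2 fold change of 0.60 ± 0.83 (limma adjusted p = 0.608). The calls of Cd93, Glp1r and Sema3c (-1.69, -5.76 and -0.93) were each lost without some single libraries and with weights per library or per group (adjusted p 0.104 to 0.261), and that of Aplnr with weights per group (0.0511). Of 7 arterial genes 1 rose and 4 fell (median -3.70), of 7 venous genes 0 rose and 3 fell (-1.50), and of 5 lymphatic genes 0 passed in either direction (-1.05). The median of all tested genes was -1.02. All 5 lymphatic genes had a higher mean normalised count in the mCherry-positive fraction, among them Flt4 at 2242 ± 1645 against 745 ± 29.1.

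A hypothesis is that the endothelial signal of the mCherry-positive fraction may come largely from aerocytes. The medians of aerocyte and general capillary genes differed by 5.11 on the log2 scale without Car4 (exact permutation test over 3003 arrangements of the 8 and 6 genes, two-sided, p = 0.00333), and by 5.30 with it (p = 0.003). Genes are not independent replicates, so the p-value describes these genes in these libraries. Whether aerocytes expressed p16 or entered the gate for another reason was not tested.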
